A study of Mus musculus with 2 samples.

How the data were processed

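Gene expression was measured in single cells from 4T1 mammary tumours of BALB/c mice, with 1 library from Ctrl and 1 from Cmas KO tumours. Per the labels, 250000 tumour cells were placed in the right inguinoabdominal fat pad and tumours were resected at day 15. The labels state that CD45-positive cells were isolated with magnetic beads, that 95% of them carried CD45 and that more than 90% were viable. According to the same labels, cells were fixed for 22 hours, 250000 cells per sample were hybridized with a 10x Genomics probe kit for the mouse transcriptome, and 10000 cells were targeted. Samples were pooled at equal numbers per the labels, and both libraries carry the same batch label. The deposited matrices hold UMI counts per gene and cell, as whole numbers with no normalization. Cell Ranger 7.1.0, Seurat 4.2.0 and the mm10 build are named in the submitters' processing notes without a role for each. The probe set version, the sequencing depth and any filter on cells made by the authors are not given in the sources used here. Each count table of the authors was checked to hold whole numbers and the same genes in the same order. No barcode was used, since a cell is known by its matrix column.

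Counts of identifiers sharing a symbol were summed, which gave 19053 gene symbols. UMIs per cell ranged from 496 to 175002 in Ctrl and from 499 to 287409 in Cmas KO. Cells with under 200 genes or over 15% mitochondrial UMIs were to be removed. No cell had under 200 genes, and 9 Ctrl cells and 0 Cmas KO cells passed the mitochondrial limit. Doublets were scored per library with Scrublet in Scanpy 1.11.5, using an expected rate that grew with the number of cells, 6.10% in Ctrl and 7.38% in Cmas KO. The automatic threshold was used unless it marked under 0.5% of cells, in which case the expected rate was used. In Ctrl it marked 2 cells, so 465 cells (6.10%) were removed at the expected rate. In Cmas KO the automatic threshold removed 227 cells (2.46%). Removal therefore differed between the libraries, and the same rate in both was tried as an alternative.

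The 16150 kept cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were ranked within each library. Scaled values were limited to 10, and 30 principal components and 15 neighbours gave a shared-neighbour graph. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 with 4 iterations gave 33 clusters. The T and NK class and the monocyte/macrophage class were clustered again, which gave 16 and 19 sub-clusters. Clusters were named from fixed marker lists for 15 classes, 6 T and NK sub-classes and 2 monocyte/macrophage sub-classes, by the highest mean scaled marker level. A class name stands for cells that are like that type by these markers. A cluster stayed unnamed if under 3 markers were raised at least 1.5 times or if its 10 leading genes held more markers of another class. It also stayed unnamed if its median UMI count was low and no marker was among its leading genes. For T and NK sub-clusters, the name also had to fit the levels of Cd4, Cd8a and Cd8b1 by a factor of 2, and NK names required CD3 genes at no more than 50% of the class mean. This last rule, and the choice to take leading genes against cells of other provisional classes, were made after the clusters had been seen.

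With 1 library per group no test between groups was possible, and cells were not used as replicates. Shares of kept cells were given with exact Clopper-Pearson intervals. UMIs were summed per class and library and expressed as counts-per-million (CPM) of the class's own sum, with exact Poisson intervals. Log2 ratios of Cmas KO over Ctrl carry exact conditional intervals, all at 95%. A gene at 0 in a library was set to 3 counts and its ratio read as a bound. Classes with at least 100 cells in each library were compared. SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and Python 3.11.15 were used. Coordinates came from GENCODE release M21.

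Gene lists were summarised by the median log2 ratio of members with at least 20 summed UMIs, where at least 5 were measured. Each median was given with its order-statistic interval over members and its percentile among 10000 random lists matched on expression in 20 bins. The 27 lists covered sialic acid synthesis and receptors, type I interferon and interferon gamma responses, and MHC class I and class II presentation. They also covered T cell, macrophage, neutrophil and dendritic cell states, chemokines, checkpoint ligands, hypoxia, cell cycle, stress and mitochondrial genes, and markers of tumour, stromal and erythroid cells and of spill-over. In all, 155 medians were computed, and all entered the alternatives. Markers, lists, filters on cells, the minimums for a comparison and the rule for named genes were fixed before the data were examined, whereas the numeric limits for naming clusters were set with the data at hand. That rule took genes with at least 100 summed UMIs and a UMI in at least 5% of cells of the class in 1 library. It named the 10 highest and 10 lowest ratios where a class had at least 300 cells in each library, and the 4 highest and 4 lowest otherwise. Cmas was added, as were members of a discussed list with the 3 largest ratios in either direction or the 3 most counts. Some results that this rule or a test gave are not reported here.

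The ratios, intervals and list percentiles were tested on simulated data for 9 classes, with 200 changed genes in each. Intervals covered the true ratio for 94.93% to 97.11% of unchanged genes. Between 2 and 7 of 100 lists without change fell outside the central 95% of random lists. The counts were drawn gene by gene from the Poisson model that the intervals assume. This therefore checks the calculation, and it does not cover variation between cells or genes that change together.

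The alternatives fixed beforehand were at least 500 genes per cell, no cell filter, no doublet removal, resolutions of 0.5 and 2, and variable genes without the response lists. Each cell was also assigned alone, genes were scaled by DESeq2 1.42.0 size factors and by TMM in edgeR 4.0.16 (R 4.3.3), and gene levels were averaged over cells. List members were also required to have at least 100 UMIs or 1 UMI in each library, and cells were thinned to 1500 UMIs for Cmas. After the data had been seen, further alternatives were added. They were doublets at the expected rate in both libraries, leading genes against all other cells, and omission of clusters of which over 95% of cells came from 1 library. The others omitted the sub-cluster led by Ccl5 or the keratinocyte-gene cluster, or counted T and NK sub-cluster 1, unnamed for its high Cd8a and Cd8b1, as CD8 T cells.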

Results

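RNA of single cells was counted in CD45-selected cells from 4T1 tumours grown in BALB/c mice. 4T1 is a mouse mammary carcinoma line. One group carried tumours with a functional sialylation pathway (Ctrl) and the other tumours lacking Cmas (Cmas KO), with 1 library per group and therefore no replicates. Intervals given with shares, levels and ratios are 95% intervals that cover counting error only. Those given with list medians are 95% intervals over the members of the list. No difference could be set against the spread between animals. The Ctrl library held 7629 cells and 41926523 unique molecular identifiers (UMIs), with a median of 4346 UMIs and 2045 genes per cell. The Cmas KO library held 9222 cells and 56830162 UMIs, with a median of 2449.5 UMIs and 1452 genes per cell. Within every class compared by gene, however, the median UMI count of kept cells was higher in Cmas KO than in Ctrl. It was 9218 against 5737.5 in monocytes and macrophages, 1734 against 1178 in neutrophils and 1652 against 1249.5 in T and NK cells. After removal of doublets and of cells over the mitochondrial limit, 7155 Ctrl and 8995 Cmas KO cells were kept, with 38561154 and 55184876 UMIs. Values compare Cmas KO with Ctrl, and ratios are log2 of Cmas KO over Ctrl.

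Cmas encodes the enzyme that activates sialic acid for transfer onto glycans (ENSMUSG00000030282). The gene lies on chromosome 6 of mm10 from 142756686 to 142775714, on the plus strand, and is annotated as protein coding. In the epithelial/tumour class, Cmas was lower in the Cmas KO library, at 25 counts-per-million (CPM; 21.6 to 28.7) against 73.1 CPM (64.6 to 82.3) in Ctrl, from 197 and 269 UMIs. The log2 ratio there was -1.55 (-1.82 to -1.28), and it was -2.21 after every cell was thinned to 1500 UMIs, which left out 11 cells in each library. The thinned value rests on few counts, with Cmas seen in 3 of 175 Cmas KO cells (1.71%; 0.355 to 4.93) and 13 of 164 Ctrl cells (7.93%; 4.29 to 13.2). Over all kept cells, most of them host immune cells, Cmas was 60.9 CPM (58.9 to 63.0) against 77.7 CPM (75.0 to 80.6), a log2 ratio of -0.35. Among host classes, log2 ratios were -0.38 in monocytes and macrophages, -0.56 in neutrophils (-0.26 with DESeq2 scaling) and -0.42 in T and NK cells. The ratio was within counting error in type 2 conventional dendritic cells (cDC2), at -0.14 (-0.58 to 0.31). Host cells carry Cmas, so no class gave a background level for the gene. The position of the Cmas probe relative to the deleted part of the gene is not given in the sources used here, so the level of the transcript does not test the knockout.

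**Figure D1:**
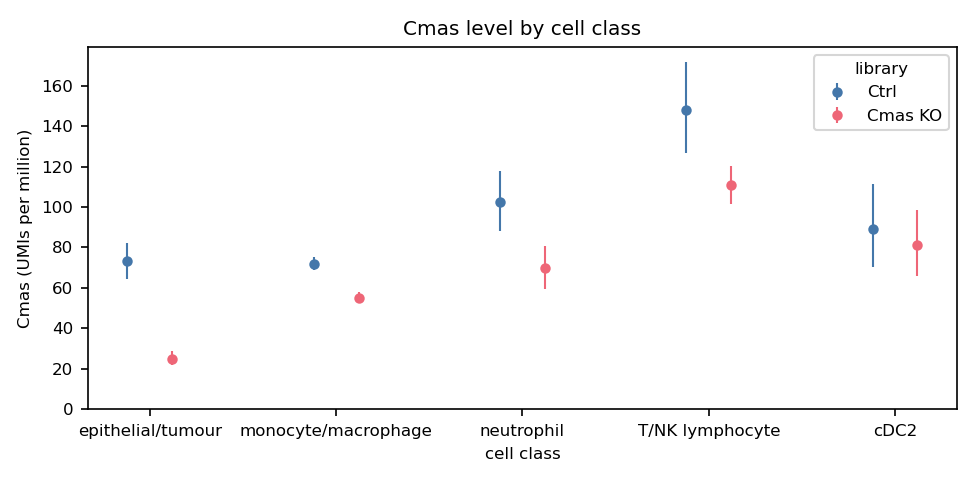
Cmas in CPM of each class's UMIs (axis), for the Ctrl and Cmas KO libraries, with exact Poisson 95% intervals. In the epithelial/tumour class the level was 73.1 in Ctrl and 25 in Cmas KO.

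Cell composition was compared because the study asked how the immune cells of tumours differ with sialylation. B cells, which make antibodies, were 17.6% of kept cells in Cmas KO and 0.349% in Ctrl, a log2 ratio of 5.66 (5.09 to 6.29). T and NK lymphocytes were more frequent in Cmas KO as well, at 26.6% against 9.17% (1.53; 1.41 to 1.66). Monocytes and macrophages, the phagocytes that made up most cells of the Ctrl library, were lower at 34.6% against 62.0% (-0.84; -0.91 to -0.78). Neutrophils, short-lived granulocytes that accumulate in 4T1 tumours, were lower at 14.0% against 19.4% (-0.46; -0.58 to -0.35), but among myeloid cells alone they were higher at 26.5% against 22.2% (0.25; 0.14 to 0.36), so the direction depends on the cells counted as the whole. Eosinophils, granulocytes of type 2 responses, were lower at 0.356% against 1.36% (-1.93; -2.55 to -1.34). The class of mast cells and basophils was higher at 0.767% against 0.363% (1.08; 0.41 to 1.79).

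Among T and NK sub-classes, conventional CD4 T cells differed most in share, at 11.5% of kept cells in Cmas KO and 0.154% in Ctrl (6.23; 5.38 to 7.23). This ratio rests on 11 Ctrl cells, and it was 7.24 with no cell filter and 1.18 without clusters mostly from 1 library. The class took in only T and NK sub-clusters 0, 8 and 14, each with Igfbp4 as its first leading gene. Sub-cluster 5, unnamed because its Cd4 was too high for CD8 T cells, held 62 Ctrl and 107 Cmas KO cells. Sub-clusters 10 and 11, unnamed for CD3 genes at T cell level, held 41 and 25 Ctrl cells and 23 and 31 Cmas KO cells. Other CD4 T cells may therefore lie outside the class, in Ctrl above all. Regulatory T cells, which restrain immune responses, were 2.52% against 1.16% (1.12; 0.75 to 1.5), and this ratio was between 0.059 and 0.18 under 5 alternative ways of building the classes. CD8 T cells, the class that holds cytotoxic T cells, were lower at 2.38% against 3.83% (-0.69; -0.95 to -0.42), although the ratio was 0.15 when each cell was assigned alone. This lower share also depends on leaving out T and NK sub-cluster 1, high in Cd8a and Cd8b1 but without a sub-class name, since with its 466 Cmas KO and 6 Ctrl cells CD8 T cells were 7.56% against 3.91% (0.95; 0.75 to 1.16). NK cells and type 1 innate lymphoid cells (NK/ILC1) were 1.66% and 1.65% (0.0064; -0.35 to 0.37). Gamma-delta and IL-17-producing T cells were 0.478% against 0.307% (0.64; -0.14 to 1.45), a difference within counting error, although the ratio was 1.86 when each cell was assigned alone. Within T and NK cells alone, conventional CD4 T cells were 43.3% in Cmas KO and 1.68% in Ctrl, and the other sub-classes were lower. CD8 T cells were 8.96% against 41.8% there (28.5% against 42.7% with sub-cluster 1), NK/ILC1 cells 6.24% against 18.0%, regulatory T cells 9.50% against 12.7% and gamma-delta and IL-17-producing T cells 1.80% against 3.35%.

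Dendritic cells present antigen to T cells. cDC2 were 1.29% of kept cells in Cmas KO and 1.93% in Ctrl (-0.58; -0.95 to -0.21), and type 1 conventional dendritic cells were 0.589% and 0.727% (-0.30; -0.88 to 0.28). Mature dendritic cells were 0.645% and 0.908% (-0.49; -1.03 to 0.04). Plasmacytoid dendritic cells, the specialised interferon producers, were higher at 0.778% against 0.503% (0.63; 0.03 to 1.25). Among myeloid cells alone, the ratio was 0.14 for cDC2 and 0.41 for type 1 conventional dendritic cells, so their lower shares of all kept cells went with the larger lymphocyte share. In the same population, monocytes and macrophages were 65.2% against 71.2%. CD45 selection removes most cells outside the immune lineage, so the next shares describe what passed it. Epithelial/tumour cells were 2.07% and 2.45% (-0.24; -0.55 to 0.06), fibroblasts 0.133% and 0.363% from 12 and 26 cells, and endothelial cells 0.178% and 0.182% from 16 and 13 cells. The fat pad that was injected holds a lymph node, and genes of lymph node stroma were higher in the last 2 classes of Cmas KO, with a log2 ratio of 1.96 (1.75 to 2.17), but 0.31 (-0.0064 to 0.62) with doublets removed at the expected rate in both libraries. With that removal the share ratios were -0.86 for epithelial/tumour cells, -2.96 for fibroblasts and -1.96 for endothelial cells.

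**Figure D2:**
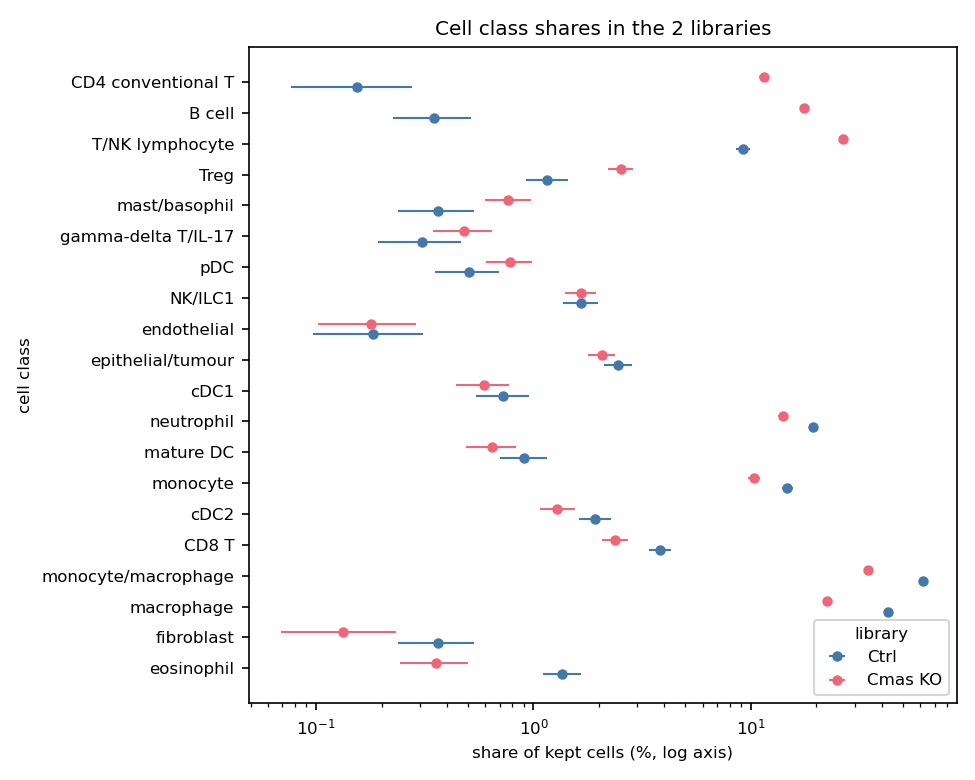
Share of kept cells in each class (percent, log axis) in the Ctrl and Cmas KO libraries, with exact binomial 95% intervals. B cells were 0.349% in Ctrl and 17.6% in Cmas KO, and monocytes and macrophages 62.0% and 34.6%.

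For several classes, the cluster with the most cells differed between the libraries. The B cells of Cmas KO lay mainly in cluster 1, with 1468 of its cells, led by Igkc, Cd79a and Ighd. Cluster 25, led by Ighg1, held 78 Cmas KO cells and 1 Ctrl cell, and cluster 29 held 41 and 0. Monocytes and macrophages were the second-best class of cluster 29, and its median was 7199 UMIs against 1551 in cluster 1. Whether cluster 29 holds doublets was not tested. The T and NK cells of Ctrl lay mainly in cluster 13 (263 cells; Nkg7, Gzmb) and cluster 11 (191 cells; Ctla4, Icos, Foxp3), whereas cluster 3 (Trac, Lef1) and cluster 14 held 1077 and 457 Cmas KO cells against 4 and 2 Ctrl cells. The largest macrophage sub-cluster was 0 in Ctrl, with 902 cells against 131, and 1 in Cmas KO, with 863 cells against 88. That of monocytes was 4 in Ctrl (453 against 118) and 3 in Cmas KO (357 against 229). The largest neutrophil cluster was 5 in Ctrl (611 against 459) and 6 in Cmas KO (604 against 434). All regulatory T cells of Ctrl lay in sub-cluster 4 (83 against 110), and sub-cluster 6 held 117 Cmas KO cells and no Ctrl cell. CD8 T cells lay mainly in sub-cluster 2 (222 and 160), and all cDC2 lay in cluster 17 (138 and 116). With 1 library per group, a cluster found mostly in 1 library may reflect that library and not a cell type. Cluster 27, led by Ctsk and Acp5, at 0.411% of Cmas KO and 0.321% of Ctrl cells, was unnamed and entered no class. Unnamed T and NK sub-clusters, at 8.02% and 2.07%, and unnamed monocyte/macrophage sub-clusters, at 1.86% and 4.53%, were left out of the sub-class comparisons but counted in the class as a whole.

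In monocytes and macrophages, interferon-response and antigen-presentation genes were higher in Cmas KO and genes of alternatively activated macrophages were lower. The type I interferon response list, genes induced by antiviral cytokines, had a median log2 ratio of 0.50 (0.39 to 0.77), with 33 of 35 measured genes higher. The interferon gamma response list had a median of 0.50 (0.25 to 0.65) and the MHC class II presentation list, which serves presentation to CD4 T cells, 0.57 (0.22 to 0.89). All 3 medians lay at percentile 100 of expression-matched random lists. With the Ctrl mix of 15 of 19 sub-clusters, the type I interferon median was 0.36 (0.18 to 0.48) and the interferon gamma median 0.16. Part of the type I interferon difference, and most of the interferon gamma difference, may therefore come from the mix or from the sub-clusters left out. No interval is given for the interferon gamma median with the Ctrl mix. These sub-clusters were found anew, in the class built with variable genes without the response lists. The response genes were not left out when that class was split, so they could help to define the sub-clusters. The alternative macrophage list, associated with wound healing and type 2 cytokines, was lower, with a median of -0.41 (-0.66 to -0.09) and 21 of 27 genes lower. No value with the Ctrl mix of sub-clusters was computed for this list.

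Ccl5, a chemokine that recruits T cells (ENSMUSG00000035042), was 987 CPM in Cmas KO against 103 CPM in Ctrl monocytes and macrophages, a log2 ratio of 3.26 (3.21 to 3.32). Ccl5 is also a marker of T and NK cells and of mature dendritic cells, and its ratio was 2.44 without the sub-cluster led by Ccl5 and 1.81 with the Ctrl mix of sub-clusters. The calpain gene Capn3 was 17.2 against 1.82 CPM (3.24; 2.83 to 3.68), and the interferon-inducible surface protein gene Ly6a was 239 against 38.4 CPM (2.64; 2.55 to 2.73). Dnase1l3, which encodes a nuclease that clears DNA of dying cells, was 110 against 23.2 CPM (2.25). Ly6i had a ratio of 2.51 (1.76 without the Ccl5-led sub-cluster), the antiviral gene Oas1g 1.81 and the receptor gene Slamf7 1.70. The highest ratios also took in markers of other classes, namely the T cell gene Il2ra at 2.37 and the B cell genes H2-Ob at 1.94 and Ighm at 1.69. T cell genes counted in this class as spill-over had a median ratio of 2.06 (1.36 to 2.96), with 12 of 12 higher, at low levels such as 6.22 against 0.653 CPM for Trac.

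Among interferon genes of the same class, Oas1a had a ratio of 1.56, the transcription factor gene Irf7 was 904 against 571 CPM (0.66), and Bst2, a plasmacytoid dendritic cell marker that encodes a restriction factor, was 0.50. Cxcl9, a chemokine induced by interferon gamma, was 261 against 113 CPM (1.21), and the guanylate-binding protein genes Gbp5 and Gbp2b had ratios of 1.03 and 0.99. The MHC class II gene H2-Aa, a cDC2 marker, was 8069 against 3606 CPM (1.16). The MHC class I presentation list had a smaller median of 0.24 (0.12 to 0.36), with H2-Q7 at 1.04, the light chain gene B2m at 0.51 and H2-K1 at 0.18. The dendritic cell maturation list had a median of 0.54 (0.11 to 0.75). Its member Il12b, a mature dendritic cell marker that encodes an interleukin 12 subunit, was 9.52 against 0.378 CPM (4.65). The inflammatory macrophage list had a median of 0.23 (-0.05 to 0.65), with the cytokine gene and neutrophil marker Il1b at 0.047, and the checkpoint ligands list 0.22 (-0.05 to 0.37).

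Among the lowest ratios in monocytes and macrophages, Retnla, a gene induced by interleukin 4, was 92.6 against 545 CPM (-2.56; -2.61 to -2.50). The neutrophil marker Cxcl3 had a ratio of -2.93. Chil3, a marker of neutrophils and of this class and a member of the alternative macrophage list, was -2.33. The metallothionein gene Mt2 was 191 against 730 CPM (-1.93), and Inhba, which encodes the activin A subunit, was 89.4 against 277 CPM (-1.63). The scaffold gene Akap5 was -2.38, Lrg1 -1.76, the transcription factor gene Sox4 -1.67, the fusion gene Dcstamp -1.66 and the lipid kinase gene Sphk1 -1.65. Arg1, the arginase of suppressive macrophages, was 2415 against 4156 CPM (-0.78). The lectin gene Clec10a, a cDC2 marker, was -1.58 and the fibronectin gene Fn1 -0.60. The lipid-associated macrophage list had a median of -0.16 (-0.37 to 0.02), in which Spp1, encoding osteopontin, was 1858 against 4728 CPM (-1.35), the lipase gene Lpl was -1.29 and the complement gene C1qa was higher at 0.57. Several of the lower genes led sub-clusters held mostly by Ctrl cells. These were Spp1 in sub-cluster 0 (902 Ctrl and 131 Cmas KO cells), Mt2 in 2 (507 and 222), Dcstamp and Inhba in 4 (453 and 118) and Cxcl3 in 9 (310 and 56). The mix of sub-clusters may therefore add to their ratios, and no value with the Ctrl mix was computed for them.

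Genes shared with neutrophils had medians of -0.34 (-0.48 to -0.13; suppressive list) and -0.61 (-1.60 to -0.29; immature granule list) in monocytes and macrophages. The same medians were -0.40 and -0.55 in macrophages alone, but -0.15 (-0.29 to 0.12) and -0.048 (-0.78 to 0.38) in monocytes alone. Unnamed sub-cluster 9, with neutrophil markers among its leading genes, held 310 Ctrl and 56 Cmas KO cells and counted in the class as a whole. The chemokines and growth factors list had a median of -0.28 (-0.58 to 0.33) with members in both directions, among them Cxcl16 at 0.72. Receptors that bind sialic acid had a median of 0.35 (-0.08 to 0.57), and in them the inhibitory receptor gene Siglece, also a neutrophil marker, was 43.9 against 20.2 CPM (1.12) and the macrophage receptor gene Siglec1 was 341 against 248 CPM (0.46). The sialic acid synthesis and transfer list had a median of 0.21 (-0.28 to 0.47). Medians were -0.16 for hypoxia and glycolysis, -0.10 for cell cycle, 0.026 for immediate early and dissociation stress and 0.11 for mitochondrial transcripts. The median was -0.57 (-1.37 to -0.13) for 4T1 and epithelial markers and -0.54 (-0.80 to 0.84) for stromal markers.

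The 2 parts of this class were also compared on their own. In macrophages, the medians were 0.51 for type I interferon, 0.42 for interferon gamma, 0.58 for MHC class II and -0.37 for alternative macrophage genes. Ccl5 was 463 against 88.1 CPM in macrophages (2.39), and the glycosyltransferase gene B3galt5 had a ratio of 1.95. Chil3, a marker of neutrophils and of monocytes and macrophages and a member of the alternative macrophage list, had a ratio of -3.43 there. The lectin genes Cd209c and Cd209f were -2.62 and -2.47, and Lbp, which encodes a lipopolysaccharide-binding protein, was -1.89. In monocytes, the blood-derived precursors of macrophages, the medians were 0.57 for type I interferon (0.36 with at least 500 genes per cell), 0.50 for interferon gamma, 0.28 for MHC class II (0.10 without the Ccl5-led sub-cluster) and -0.18 for alternative macrophage genes. Ccl5 was 2681 against 175 CPM in monocytes (3.94), and 2.07 without the Ccl5-led sub-cluster, which held 157 Cmas KO and 22 Ctrl cells. The chemokine gene Ccl8 was 771 against 168 CPM (2.20), the acute-phase gene Saa3 had a ratio of 2.27 and the protease inhibitor gene Cst7 2.30, and without that sub-cluster these ratios were 0.76, 0.28 and 0.73. Akap5 in monocytes was -2.81 (-1.62 with at least 500 genes per cell), Dcstamp -1.85, the chemokine gene Cxcl14 -1.68 and the ecto-nucleotidase gene Nt5e -1.43. Cd209f was a leading gene of macrophage sub-cluster 14, with 100 Ctrl and 9 Cmas KO cells, and Dcstamp of monocyte sub-cluster 4, with 453 and 118. The mix of sub-clusters may therefore add to the lower ratios in both parts, which was not tested.

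**Figure D3:**
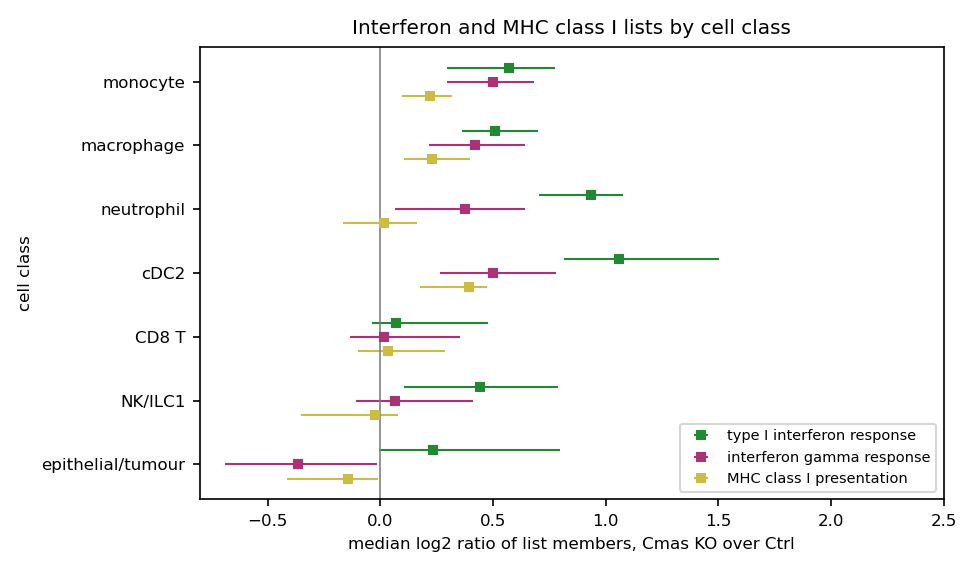
Median log2 ratio of Cmas KO over Ctrl (axis) of the type I interferon, interferon gamma and MHC class I lists in 7 classes, with 95% order-statistic intervals over list members. The type I interferon median was 1.06 in cDC2, 0.93 in neutrophils and 0.068 in CD8 T cells, and the interferon gamma median was -0.37 in the epithelial/tumour class.

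In neutrophils, type I interferon genes were higher in Cmas KO and granule genes of immature neutrophils were lower. The type I interferon median was 0.93 (0.70 to 1.08), with 31 of 34 genes higher. The immature neutrophil granule median was -1.62 (-3.19 to -1.14), with 19 of 19 genes lower. The median of all genes in this class was -0.29, for a reason that was not tested. Scaling by DESeq2 and TMM raised the ratios here by 0.29 and 0.27 over scaling to the UMI sum. With DESeq2 scaling the type I interferon median was 1.23, and the granule median ranged from -1.74 to -1.15 over the alternatives.

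The antiviral genes Ifit3, Ifit2, Ifit1 and Ifit3b had ratios of 1.83, 1.70, 1.61 and 1.58 in neutrophils. Rsad2, which encodes the antiviral enzyme viperin, was 3655 against 1152 CPM (1.67; 1.60 to 1.73), and the ubiquitin-like modifier gene Isg15 was 6481 against 3718 CPM (0.80). H2-Q7, an MHC class I gene, had a ratio of 1.79, the transcription factor gene Batf 1.63, Oas1a 1.52 and the lectin receptor gene Clec4a3 1.41. H2-Aa, a cDC2 marker, was 465 against 169 CPM (1.46), and 0.80 with no doublets removed. The interferon gamma median was 0.38 (0.07 to 0.64; 0.67 with DESeq2 scaling), with the chemokine gene Cxcl10 at 1.39, Gbp2 at 0.69 and Cd274, which encodes PD-L1, at 0.49. The MHC class II median was 0.62 (-0.08 to 1.46), but -0.052 with doublets removed at the expected rate in both libraries, and that of MHC class I 0.015 (-0.17 to 0.17; 0.31 with DESeq2 scaling).

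Ngp, a secondary granule gene of neutrophil precursors (ENSMUSG00000032484), was 85.9 against 1237 CPM in neutrophils (-3.85; -4.06 to -3.64). Only 0.951% of Cmas KO and 6.21% of Ctrl neutrophils held a UMI of Ngp, and 3.09% and 5.92% held one of Ltf. The levels of these genes thus rest on a small part of the class. Camp, which encodes cathelicidin, was 17.9 against 387 CPM (-4.44), the lactoferrin gene Ltf 56.6 against 605 CPM (-3.42) and the surface antigen gene Cd177 49.2 against 466 CPM (-3.24). Ly6g, the lineage antigen of mouse neutrophils, was 29.3 against 151 CPM (-2.37), and Lcn2, also an epithelial/tumour marker, had a ratio of -1.19. The secretory kinase gene Fam20c was -3.04, the stress factor gene Atf5 -2.57, the glucokinase gene Adpgk -2.23 and the cell cycle factor gene Tfdp1 -2.13. Anxa3, a mature dendritic cell marker, and Ffar2, a cDC2 marker, both had ratios of -2.31. The neutrophil suppressive median was -0.0028, with 14 of 28 genes higher, and within it Arg1, a monocyte and macrophage marker, was -1.34 and Nos2 -1.63. Medians were 0.95 for mitochondrial transcripts, 0.39 for immediate early and dissociation stress and -0.35 for hypoxia and glycolysis (-0.058 with DESeq2 scaling). T cell genes counted as spill-over had a median of 2.87 (1.38 to 4.43) in neutrophils, with 11 genes higher and 0 lower.

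In cDC2, interferon genes were higher in Cmas KO and alternative activation genes were lower. The type I interferon median was 1.06 (0.81 to 1.5), with 33 of 33 genes higher, and the interferon gamma median was 0.50 (0.26 to 0.78; 0.32 with at least 500 genes per cell). The MHC class I median was 0.39 (0.18 to 0.47). The alternative macrophage median was -0.48 (-1.06 to -0.07; -0.24 with at least 500 genes per cell), with 20 of 27 genes lower, and the cell cycle median was -0.50 (-0.76 to -0.10; -0.077 with at least 500 genes per cell).

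Ly6a was 489 against 19.6 CPM in cDC2 (4.64; 3.95 to 5.43), from 592 and 17 UMIs. Ccl5, a marker of T cells and mature dendritic cells, was 477 against 35.8 CPM (3.73), with ratios of 1.92 to 2.88 under 5 alternatives. Ets1, a lymphocyte transcription factor gene, had a ratio of 3.28, and 0.76 to 1.94 under 3 alternatives. T cell genes counted as spill-over moved the same way, with a median of 2.04 (1.17 to 4.07) that was between 0.54 and 0.71 under 3 alternatives. Among interferon genes, Ifi44 had a ratio of 2.59, Ifitm3 was 925 against 265 CPM (1.81), Cxcl10 had a ratio of 2.06 and Gbp2 1.42. H2-Q7 was 1.27 and B2m 0.89. Chil3, a marker of neutrophils and of monocytes and macrophages, was lower at 1 UMI against 274 UMIs (-8.58; -13.89 to -6.09), and its ratio was -4.65 with no doublets removed and -5.50 with at least 500 genes per cell. The monocyte and macrophage markers Ccl8 and Ccl12 had ratios of -4.12 and -4.09, with Ccl8 at -1.06 with no doublets removed and -6.98 with doublets at the expected rate, and Inhba was -3.08 (-1.84 at resolution 2). Retnla was 1577 against 6727 CPM (-2.09), and the monocyte and macrophage markers Spp1 and Arg1 had ratios of -2.66 and -1.76. The MHC class II median was 0.18, the dendritic cell maturation median 0.28 and the lipid-associated median -0.55.

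In T and NK lymphocytes as a whole, genes of naive cells were higher in Cmas KO and genes of cytotoxic cells were lower. The naive and memory T cell list had a median of 2.43 (1.39 to 2.90), with 21 of 23 genes higher. The cytotoxic effectors list had a median of -0.91 (-1.40 to -0.77), with 24 of 28 genes lower. Without the clusters of which over 95% of cells came from 1 library they were 0.84 and -0.079. Those clusters were picked by the difference between the libraries, so this does not separate the mix of cells from change within cells. The T cell exhaustion list, genes of chronically stimulated T cells, had a median of -0.70 (0.10 without those clusters), and the activated regulatory T cell list -0.68 (0.17 without them).

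Ccr7, a mature dendritic cell marker that encodes the receptor guiding T cells into lymph nodes, was 1642 against 150 CPM in T and NK cells (3.45), and Klf2, a factor of circulating T cells, was 2174 against 445 CPM (2.29). Igfbp4 was 669 against 37.0 CPM (4.18; 3.74 to 4.65), and 0.069 without the clusters mostly from 1 library. Without those clusters, the Notch regulator gene Dtx1 was 2.09 in place of 4.12, Tdrp 1.47 in place of 4.06, the receptor gene Vipr1 0.90 in place of 3.86, Dzip1 1.47 in place of 3.8, the actinin gene Actn1 1.08 in place of 3.78 and Pdlim4 0.23 in place of 3.69. H2-Ob, a B cell marker, had a ratio of 5.43 (2.94 to 10.74) from 186 UMIs against 1. Rapgef4 had a ratio of 4.98 (3.11 to 8.03) from 271 UMIs against 2, and Ggt5 3.91 (2.02 to 6.97) from 129 against 2. Without those clusters, H2-Ob was 1.68 and Ggt5 1.09, and Rapgef4 had 3 UMIs against 1, too few for a ratio. St6gal1, which encodes a sialyltransferase of lymphocytes, had a ratio of 2.66, within a sialic acid synthesis and transfer median of 0.082.

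Gzmb and Gzma, which encode granzymes of killer cells, were 991 against 7367 CPM (-2.89; -2.94 to -2.84) and 609 against 4295 CPM (-2.82; -2.88 to -2.75) in T and NK cells. Without the clusters mostly from 1 library they were -1.72 and -1.67. The granzyme gene Gzmc was -2.60 (-1.44 without them), the metallothionein genes Mt2 and Mt1 -2.75 (-1.74) and -2.49 (-1.44), and the kinase gene Styk1 -2.52 (-1.37). AA467197 was -2.41 (-1.39), Tmem273 -2.35 (-1.39), Cables1 -2.32 (-1.20) and the mitotic kinase gene Nek2 -2.23 (-1.13), with the values without those clusters in brackets. Nkg7, a granule gene of killer cells, was -1.60. The cell cycle median was -0.86 (0.11 without those clusters), that of hypoxia and glycolysis -0.61 (-0.11) and that of mitochondrial transcripts 1.13 (0.28). The immediate early and dissociation stress median was higher at 0.35 (0.22 to 0.54). Neutrophil markers counted as spill-over had a median of -0.73 (-0.37), with 13 of 13 lower.

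Within CD8 T cells, Gzma and Gzmb were lower in Cmas KO. The cytotoxic effectors median was -0.31 (-0.56 to -0.02), with 19 of 26 genes lower, and 0.023 as a mean over cells. The naive and memory median was 0.83 (-0.0043 to 1.38), an interval that reached below 0, with 14 of 20 genes higher. The cell cycle median was 0.40 (0.24 to 0.64), with 31 of 34 genes higher, and 0.058 with at least 500 genes per cell. The exhaustion median was 0.15 (-0.21 to 0.76), that of immediate early and dissociation stress 0.25 (-0.037 to 0.44) and that of type I interferon 0.068. With T and NK sub-cluster 1 counted as CD8 T cells, the medians were -0.88 for cytotoxic effectors, 2.55 for naive and memory genes, -0.53 for exhaustion, 0.60 for stress and, in the other direction, -0.30 for cell cycle.

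Gzma was 1622 against 6136 CPM in CD8 T cells (-1.92; -2.00 to -1.84), Gzmb 3520 against 11270 CPM (-1.68) and Nkg7 -0.69. Tcf7, which encodes a factor of naive and stem-like T cells, was 95.7 against 12.5 CPM (2.94). The enkephalin gene Penk had a ratio of 2.64 that ranged from 1.58 to 5.24 under alternatives, and the B cell marker Ighm 2.49. Slamf6, a receptor gene of memory-like T cells, was 2.34, the exhaustion factor gene Tox 1.79, the chemokine gene Xcl1 1.48 and the checkpoint receptor gene Pdcd1 -0.21. Foxp3, the factor of regulatory T cells, was 86.5 against 20.3 CPM (2.09). The monocyte and macrophage marker Fn1 had a ratio of -2.36, Styk1 -2.09 and the matrix gene Emilin2 -1.74. With T and NK sub-cluster 1 counted as CD8 T cells, Gzma was -2.75, Tcf7 4.36, Ighm 3.59, Fn1 -1.75 and Styk1 -2.88.

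In NK/ILC1 cells, the type I interferon median was 0.44 (0.11 to 0.79), with 16 of 20 genes higher. The immediate early and dissociation stress median was higher as well, at 0.22 (0.059 to 0.53), with 24 of 33 genes higher. The same list was higher in neutrophils (0.39) and in T and NK cells as a whole (0.35). Handling may have added to the differences in all of these classes, which was not tested. Cd69, an early activation gene, was 355 against 116 CPM (1.61; 0.85 to 2.47), and the signalling inhibitor gene Smad7 was 474 against 159 CPM (1.57). Hnrnpa2b1 had a ratio of 1.48 and Sertad1 1.14. Gzmc was 212 against 2666 CPM in NK/ILC1 cells (-3.66; -4.07 to -3.26), while Gzma and Gzmb were -0.56 and -0.60. The tubulin gene Tubb5 was -1.37, Prelid1 -0.94 and Txndc11 -0.94. The cytotoxic effectors median was 0.10, the exhaustion median -0.084 and the interferon gamma median 0.066.

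In the epithelial/tumour class, Cldn3 and Cldn7 were far lower in Cmas KO, interferon gamma genes were lower and cell cycle genes were higher. The interferon gamma median was -0.37 (-0.69 to -0.01), with 24 of 34 genes lower, and it was -0.94 with doublets removed at the expected rate in both libraries, -0.21 without cluster 31 and -0.13 as a mean over cells. The cell cycle median was 0.48 (0.23 to 0.74), with 27 of 34 genes higher. The type I interferon median was 0.24 (-0.0048 to 0.80) and that of MHC class I -0.14 (-0.42 to -0.01), at percentile 19.96 of random lists and therefore not set apart from other genes. The mitochondrial transcript median was 0.47 (0.19 to 0.81), with 11 of 13 genes higher, and -0.35 as a mean over cells. These values rest on 175 Ctrl and 186 Cmas KO cells that passed CD45 selection.

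Cldn3, a tight junction gene of epithelial cells (ENSMUSG00000070473), was 2.03 CPM in Cmas KO against 594 CPM in Ctrl tumour cells (-8.19; -9.0 to -7.49). The related gene Cldn7 was 1.78 against 359 CPM (-7.66; -8.53 to -6.91). Cldn4, another claudin gene, which was chosen after its values were seen, was 2777 against 2214 CPM (0.33). The bicarbonate transporter gene Slc4a4 had a ratio of -6.88 (-9.94 to -4.99) from 2 UMIs against 110, and the calcium pump gene Atp2c2 was 4.82 against 87.2 CPM (-4.18). Under alternatives the Cldn3 ratio ranged from -9.71 to -5.37. Msmp, which encodes a secreted microseminoprotein, had a ratio of 8.11 (5.62 to 13.41) from 590 UMIs against 1. The keratin gene Krt6a was 509 against 1.09 CPM (8.87), Cst6 was 600 against 8.69 CPM (6.11), and Igfbp5, at 0 UMIs in Ctrl, had a log2 ratio of at least 7.56 by its lower 95% limit (7.86 against a floor of 3 counts). The differences of Krt6a, Cst6 and Igfbp5 were lost with doublets removed at the expected rate in both libraries. Cst6 was then -0.46, and Krt6a and Igfbp5 had at most 1 UMI in each library, too few for a ratio. The Cmas KO counts of Krt6a, Cst6 and Igfbp5 came mainly from the 16 cells of cluster 31, which carried keratinocyte genes. The highest cell for each gene there held 41.4% of the Krt6a counts, 87.8% of the Cst6 counts and 87.6% of the Igfbp5 counts.

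Nlrc5, the activator of MHC class I genes, was 115 against 273 CPM in tumour cells (-1.25), and Gbp2 was 369 against 644 CPM (-0.80). Gbp8 had a ratio of -1.60, Gbp4 -1.33, the peptide-loading gene Tapbp -0.86 and H2-K1 -0.42, whereas H2-Q7 was 0.96, B2m 0.15 and the adhesion gene Icam1 2.16. Ifitm3 was 775 against 303 CPM (1.36) and Ifit3 had a ratio of 1.74. The mitotic genes Plk1, Cenpe and Cenpf had ratios of 1.32, 1.35 and 1.30, and Pcna was -0.72. The heat shock gene Hspa1a was 223 against 20.4 CPM (3.45), although 23 of 35 genes of its immediate early and dissociation stress list were lower (median -0.16; -0.32 to 0.021), and the hypoxia gene Car9 had a ratio of -1.18. Among sialic acid genes, with a list median of 0.26 (-0.19 to 0.66), the sialyltransferase gene St6galnac2 was 4.19 against 18.7 CPM (-2.16) and the lyase gene Npl 30.3 against 4.89 CPM (2.63). The 4T1 and epithelial marker median was 0.34 (-0.51 to 2.12; -0.26 without cluster 31). The stromal marker median was 0.96 (0.17 to 3.81), and -0.20 with doublets removed at the expected rate. Of the erythroid markers, at most 1 gene (Car2) was measured in any class, so that list gave no median.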

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

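Of the tests in this part, that of doublet removal, and the lymph node test with other doublet removal, were chosen only after the result was seen. Differences between classes were not tested, since each class gave 1 ratio from 1 library per group.

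Cells that no sub-class name covered, and that counted only in the T and NK or monocyte/macrophage class as a whole, were more frequent in the Cmas KO library, beyond counting error, in 5 sub-clusters. T and NK sub-cluster 1, with naive T cell genes beside Cd8a and Cd8b1, was 5.18% of kept cells against 0.0839% in Ctrl, and counted as CD8 T cells it turned their share ratio from -0.69 to 0.95. T and NK sub-cluster 12, with myeloid genes, was 0.467% against 0.0419%, and T and NK sub-cluster 13, with B cell genes, was 0.456% against 0.0140%. Monocyte/macrophage sub-cluster 16, with T cell genes, was 0.945% against 0.196%. Monocyte/macrophage sub-cluster 18, with B cell genes, was 0.289% against 0%. Of the other unnamed sub-clusters, monocyte/macrophage sub-cluster 9 was lower in Cmas KO, at 0.623% against 4.33%, T and NK sub-cluster 10 was 0.256% against 0.573%, and T and NK sub-cluster 5 was 1.19% against 0.867% with intervals that overlap. T and NK sub-clusters 12 and 13 and monocyte/macrophage sub-clusters 16 and 18 carried genes of another lineage, as doublets would. Doublet removal took 2.46% of Cmas KO cells, against an expected rate of 7.38%, and 6.10% of Ctrl cells. Doublets left in may therefore add to the Cmas KO shares of these sub-clusters, which was not tested.

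Some gene lists had median intervals on opposite sides of 0 in different classes. The MHC class I median was higher by 0.53 in cDC2 and by 0.38 in monocytes and macrophages than in the epithelial/tumour class, where it lay at percentile 19.96 of random lists and was -0.048 as a mean over cells, so a lower level there is not shown. The interferon gamma median was higher than in the epithelial/tumour class by 0.87 in cDC2, by 0.87 in monocytes and macrophages and by 0.74 in neutrophils, and in that class it was -0.13 as a mean over cells. The cell cycle median of the epithelial/tumour class exceeded that of T and NK cells by 1.34, of cDC2 by 0.98 and of monocytes and macrophages by 0.58. The cell cycle median of CD8 T cells exceeded that of T and NK cells by 1.26, of cDC2 by 0.91 and of monocytes and macrophages by 0.50. The opposite directions of cell cycle genes were not stable where T and NK cells or CD8 T cells were compared. The median was 0.11 in T and NK cells without clusters mostly of 1 library. In CD8 T cells it was 0.058 with at least 500 genes per cell, 0.093 at resolution 2 and -0.30 with T and NK sub-cluster 1. No alternative reversed the median of the epithelial/tumour class, of cDC2 or of monocytes and macrophages, although that of cDC2 was -0.077 with at least 500 genes per cell. The epithelial/tumour values rested on 175 and 186 cells.

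B cells and T cells with naive-cell genes were found almost only in the Cmas KO library. Doublet removal that differed between the libraries was argued against, since the B cell ratio was 5.82 with no doublets removed. Blood as a source is not weighed here. Lymph node tissue carried into the sample may be a source, as 15 stroma genes (1 of them, Clu, also a class marker) had a log2 ratio of 1.96 in endothelial cells and fibroblasts, from 1086 UMIs in 28 cells against 223 in 39, with Ccl21a at 438 against 0, Ackr1 at 216 against 13, Cxcl13 at 34 against 0, and Madcam1 at 0 in both. This test does not decide, because with doublets removed at the expected rate in both libraries the ratio was 0.31 (-0.0064 to 0.62), from 137 UMIs in 8 cells against 223 in 39. Lymphoid tissue formed within the Cmas KO tumour could carry the same stroma genes and stays open as untested. A response of lymphocytes to the missing sialylation was not tested either, and the stroma genes do not bear on it.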

How the results depend on the processing

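The alternatives with doublets at the expected rate in both libraries, with leading genes against all other cells, and without clusters mostly of 1 library, the keratinocyte-gene cluster or the Ccl5-led sub-cluster were tests chosen only after the results were seen, as was the one that counts T and NK sub-cluster 1, unnamed and high in Cd8a and Cd8b1, as CD8 T cells. No paired analysis was possible because each group had 1 library. Where no cause is named, the cause was not tested.

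The B cell share ratio was between 5.60 and 5.82 under the alternatives that gave a value, and that of Cmas in tumour cells between -2.21 and -1.46. In monocytes and macrophages, the medians ranged from 0.50 to 0.59 for type I interferon, 0.45 to 0.54 for interferon gamma, 0.53 to 0.58 for MHC class II and -0.49 to -0.37 for alternative macrophage genes. Outside these ranges, the Ctrl mix of sub-clusters gave 0.36 for type I interferon and 0.16 for interferon gamma. The neutrophil granule median ranged from -1.74 to -1.15 and the cDC2 type I interferon median from 0.84 to 1.33. Of 199 alternative share ratios, 155 stayed within the counting interval, 39 lay outside it with no change of a clear direction, and 5 reversed. Of 1491 alternative list medians, set against the interval over list members, these numbers were 1440, 45 and 6. Among 1094 alternative ratios of named genes, set against the counting interval, they were 917, 176 and 1. The 135 list medians that could be given with members of at least 100 UMIs, and the 155 with members of 1 UMI in each library, stayed within their intervals. Where both libraries held at most 3 UMIs of a gene no ratio was given, a limit applied to the alternatives after their values had been seen, which took out 4 ratios, 3 of which had been reversals. No share ratio could be given for cDC2 at resolution 0.5 or for B cells without clusters mostly of 1 library.

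With at least 500 genes per cell, the share ratio was -0.92 for monocytes and macrophages together, -1.10 for macrophages, -0.78 for monocytes and -0.21 for neutrophils, and the cell cycle median was -0.077 in cDC2 and 0.058 in CD8 T cells. With no cell filter, share ratios were 7.24 for conventional CD4 T cells, -0.42 for CD8 T cells, 0.13 for regulatory T cells and -0.20 for monocytes. With no doublets removed, they were -0.33 for CD8 T cells and 0.11 for regulatory T cells, while spill-over medians were -1.55 for neutrophil markers in T and NK cells and 0.54 for T cell markers in cDC2. Resolution 0.5 gave 0.059 for regulatory T cells and -0.65 for monocytes. Variable genes without the response lists gave -0.98 for cDC2, 0.12 for regulatory T cells, -1.05 for macrophages and -0.30 for monocytes. With each cell assigned alone, the ratio was 1.86 for gamma-delta T cells, -1.06 for macrophages and, reversed, 0.15 for CD8 T cells.

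At resolution 2, the activated regulatory T cell median in T and NK cells was -0.81, T cell spill-over in cDC2 0.71, the CD8 cell cycle median 0.093 and the monocyte chemokine median 0.29. As a mean over cells, the T and NK medians were -1.15 for activated regulatory T cell genes and -1.19 for cell cycle, and those of tumour mitochondrial transcripts (-0.35) and CD8 cytotoxic effectors (0.023) reversed. Thinning gave Cmas ratios of -0.23 in all kept cells and -2.21 in tumour cells. In neutrophils, DESeq2 size factors and TMM move every gene by 1 amount by construction. With DESeq2, the medians were 1.23 for type I interferon, 0.67 for interferon gamma, 0.31 for MHC class I, 0.29 for suppressive genes, -0.058 for hypoxia, 0.69 for stress and 1.24 for mitochondrial transcripts. With TMM, the first 6 were 1.20, 0.65, 0.29, 0.27, -0.082 and 0.66.

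With doublets at the expected rate in both libraries, share ratios were -1.96 for endothelial cells, -0.86 for tumour cells, -2.96 for fibroblasts, 0.18 for regulatory T cells, -0.81 for macrophages and -0.70 for monocytes. Spill-over medians were -1.83 and -2.22 for neutrophil markers in T and NK and in CD8 T cells and 0.70 for T cell markers in cDC2. Cell cycle medians were -0.22 in monocytes and macrophages together, -0.25 in macrophages and -0.39 in monocytes. In tumour cells, the interferon gamma median was -0.94, and the stromal median (-0.20) and Cst6 (-0.46) reversed. Krt6a at 1 UMI in each library and Igfbp5 at 1 UMI against 0 gave no ratio there, so their differences were lost with no direction left. Leading genes against all other cells gave share ratios of -0.70 for monocytes and macrophages together, -0.59 for macrophages and -0.84 for monocytes.

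Without clusters mostly of 1 library, 38 Ctrl and 3354 Cmas KO cells were left out, which by construction raises the Cmas KO share of every class that lost none. Share ratios were then 0.44 for T and NK cells, 1.18 for conventional CD4 T cells, -0.028 for CD8 T cells, 0.67 for NK/ILC1, 0.74 for regulatory T cells, 0.36 for type 1 conventional dendritic cells, 0.17 for mature and 1.29 for plasmacytoid dendritic cells, -1.26 for eosinophils, 0.42 for tumour cells, -0.21 for monocytes and macrophages together and -0.27 for macrophages. The ratios of cDC2 (0.085), neutrophils (0.20) and monocytes (0.16) reversed. T and NK medians were 0.40 for type I interferon, -0.079 for cytotoxic effectors, 0.10 for exhaustion, 0.84 for naive and memory genes, -0.11 for hypoxia, 0.28 for mitochondrial transcripts and -0.37 for neutrophil spill-over, and those of activated regulatory T cell genes (0.17) and cell cycle (0.11) reversed. Rapgef4 in T and NK cells, at 3 UMIs against 1, gave no ratio. Without the keratinocyte-gene cluster, Krt6a gave no ratio, at 1 UMI in each library, so its difference was lost, and the tumour stromal median was 0.072. Without the Ccl5-led sub-cluster, the monocyte MHC class II median was 0.10.

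With T and NK sub-cluster 1 counted as CD8 T cells, their share ratio (0.95) and cell cycle median (-0.30) reversed, and their medians were -0.88 for cytotoxic effectors, -0.53 for exhaustion, 2.55 for naive and memory genes, -0.53 for hypoxia, 0.60 for stress and 0.98 for mitochondrial transcripts. With doublets at the expected rate, the neutrophil MHC class II median was -0.052 and the ratio of lymph node stroma genes 0.31 in place of 1.96.

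Cell number limited the smaller classes, since eosinophils, fibroblasts and endothelial cells held under 100 cells in each library and, apart from 15 lymph node stroma genes, were not compared by gene.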

Other observations

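Of the tests in this part, the one of fewer tumour cells or more RNA of other cells was chosen only after the result was seen, and its bound was set a second time because the first bound gave no decision. For the mix of sub-clusters, the comparison of the interval with a limit was added when the test was run.

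The 78 Cmas KO cells of the Ighg1-led B cell cluster carried germinal centre genes, which were chosen after the cluster had been seen. Mef2b was 449 CPM there and 5.65 CPM in the 1468 Cmas KO cells of cluster 1. In the same order, Bcl6 was 308 and 243 CPM, S1pr2 320 and 5.25 CPM, Rgs13 327 and 6.86 CPM, Mybl1 378 and 3.63 CPM, Basp1 864 and 35.1 CPM, Gcsam 172 and 1.21 CPM and Fas 41.3 and 14.1 CPM.

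Ccl5 and interferon-response genes were higher in monocytes and macrophages of Cmas KO. RNA or doublets of the T and NK class taken as a whole were argued against as the source of Ccl5. The 2296 T cell gene UMIs in monocytes and macrophages predict 0.761% of their 31413 Ccl5 UMIs. The rate came from all 2389 T and NK cells of Cmas KO, of which 1035 were conventional CD4 T cells, and from T cell genes only. Spill-over from NK cells or cytotoxic T cells alone was therefore not weighed. A different mix of sub-clusters may account for part of the pattern, and for most of the interferon gamma difference. The type I interferon median was 0.36 (0.18 to 0.48) with the Ctrl mix of 15 of the 19 sub-clusters found anew for this test, against 0.50 for the whole class. This interval spans the value at which most of the difference would be lost, so for type I interferon genes the mix and a change within sub-clusters cannot be told apart. With the Ctrl mix, the interferon gamma median was 0.16 against 0.50 and the Ccl5 ratio 1.81 against 3.28, and an effect of the missing sialylation on these cells stays untested.

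Cldn3, Cldn7 and Krt6a lay far apart in the epithelial/tumour class between the libraries. Skin keratinocytes were argued against as the source of the Cldn3 difference, since Cldn3 was -9.68 (-11.31 to -8.46) without the keratinocyte-gene cluster. The Krt6a difference, in contrast, lay in that cluster, where 16 Cmas KO cells held 4012 UMIs, against 1 UMI in each library in cluster 15. Fewer tumour cells, or more RNA of other cells, would lower other epithelial genes as much as Cldn3, but the median of 14 such genes was -0.13 (-1.01 to 0.34), with Epcam at 0.31, Krt18 at 0.53 and Krt8 at -0.27. A candidate explanation is that the Cmas KO cells came from a clone of 4T1 that differs in Cldn3 and Cldn7 for reasons other than Cmas, which was not tested and which the design cannot separate from the knockout. In cluster 15 of this class, Cldn7 was 1.33 against 368 CPM, Atp2c2 1.48 against 88.5 CPM, Epcam 1026 against 827 CPM and Msmp 87.3 against 0.278 CPM.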
